A study of Homo sapiens with 6 samples.

How the data were processed

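RNA was measured by sequencing of poly(A) RNA (SMARTER mRNA-seq kit, from 1 µg of total RNA) in KGN cells, a human cell line from an ovarian granulosa cell tumour, 48 h after transfection. The 6 libraries formed 2 groups of 3, negative control siRNA and SNHG5 siRNA. Both deposited tables held these 6 libraries and 0 columns of other samples. Per the labels, the authors trimmed reads with Trimmomatic and used genome build GRCh38; the version of Trimmomatic, the aligner, the counting program and the gene annotation were not given in the sources used here.

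The deposited count table held counts (whole numbers, not normalised by the authors) for 20030 gene names. The deposited FPKM table held FPKM, fragments scaled to gene length and library size by the authors with a tool not given in the sources used here. The FPKM were not a fixed multiple of the counts, since 410 to 478 genes per library were at 0 in exactly 1 of the 2 tables, so the counts were used for every main value and the FPKM as an alternative. In the count table, 27 names read as calendar dates, as spreadsheet programs make from some gene symbols, and these held 0.257% of all counts; they were kept in the tests and never named. A further 4 entries shared their name with another entry. In all, 19277 names matched GENCODE v29, and 18591 of the names had an annotated 3' UTR. SNHG5 and the snoRNAs in its introns, SNORD50A and SNORD50B, were not analysed here.

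Total counts ranged from 18232634 to 22088913 per library. A count of 3, taken as the detection floor, was 0.136 to 0.165 CPM (counts scaled to library size) in the 6 libraries. Intervals of count ratios and floors cover counting error only. Replicates were compared as the labels give them; the labels do not say whether they were separate cultures, so each p measures only the spread between these samples.

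Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors from 0.998 to 1.003, and 12508 genes that passed filterByExpr were tested with edgeR's quasi-likelihood test (2-sided), SNHG5 siRNA minus control siRNA. Another 7522 names were not tested. P was adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. CPM are given as mean ± SD (n = 3). Log2 fold changes come from the edgeR fit; folds were computed from the same fit. Counts with the spread of these libraries were also simulated, with few genes changed. There the test recovered 32 of 49 genes changed 1.25-fold, 43 of 50 changed 1.5-fold and 49 of 50 changed 2-fold. It called 10 of 12204 unchanged genes. In the data 5026 genes passed, so the unadjusted p that met the threshold was larger. The simulated rates therefore do not give the share of errors among those calls.

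Before the data were examined, 35 gene lists were written for pathways, gene groups and cell types that fit a granulosa line treated with siRNA; 866 of their 902 symbols were found, 32 under another symbol. Lists with at least 5 tested members, 30 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), adjusted over the 30 lists. Camera with an estimated correlation and fry were run beside it. Of the lists, 11 passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.103; 7 at an unadjusted p under 0.05) and 15 by fry. Member counts are given over all genes tested and adjusted over the list alone.

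Genes with GTGCAAT, the 7-base site of miR-92a-3p, in an annotated 3' UTR were compared with the other tested genes. Each 7-base word was also scored across 12214 tested genes with a 3' UTR, as the z of the difference in log2 fold change between genes with and without the word after a trend on 3' UTR length was removed. This is a description across genes, which are not independent replicates. With the values shuffled over genes, 20 of 20 words of 240 to 260 genes that were lowered by 0.2 came out lowest. Shuffling removes trends that many words share, such as that on GC content. The result therefore does not show that such a word would lead in the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the scan, and matplotlib 3.10.9 for the plots.

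The rule for named genes was written before the data were examined. It took SNHG5 and CDKN1C always, with SNORD50A and SNORD50B if listed. It took the 8 largest rises and 8 largest falls among passing genes with a mean CPM of at least 5 and no overlap of CPM between the groups. It took the 4 smallest p in each direction, up to 4 passing members of each list by absolute log2 fold change, and, in lists with fewer than 2 passing members, the 2 with the highest mean CPM. STAR, CYP11A1, CYP19A1, FSHR, FOXL2, CCND1, CCND2, CDKN1A and MKI67 were named always. Passing members behind a count of 3 or fewer in a called list (CXCL8, SOD2, TRIB3, IFI44, SAMD9, LOX and MYC), XPC and the neighbours of SNHG5 were named after their values were seen. A few genes that the rule took are not reported here.

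Alternatives were other scalings (DESeq2 1.42.0 size factors, library totals, upper quartile), no filter or a minimum of 1 CPM in 3 libraries, DESeq2's Wald test, limma voom, limma on log2 of FPKM plus 1 or plus 0.1, a replicate block, removal of trends on gene length, a stricter threshold of 0.01, and leaving out each library in turn. Removal of trends on GC content and leaving out genes with the leading words of the scan were added after the data were seen.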

Results

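The data were mRNA profiles of KGN cells, a human line from an ovarian granulosa cell tumour, in 3 libraries with negative control siRNA and 3 with siRNA against SNHG5, a long noncoding RNA whose introns hold snoRNAs. Total counts were 20479618, 20353451 and 18232634 in control siRNA replicates 1, 2 and 3, and 22088913, 19869165 and 19417645 in SNHG5 siRNA replicates 1, 2 and 3. Spearman correlations of log2 CPM were 0.996 to 0.998 within groups and 0.987 to 0.989 between groups, and the leading principal component, with 61.6% of the variance, parted the groups. SNHG5 siRNA replicate 2 stood apart from its replicates, with a chi-square per degree of freedom of 8.66 and 8.89 against them, where the other pair of that group had 1.92 and the control pairs 3.11 to 4.42.

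The comparison of SNHG5 siRNA with control siRNA asked how KGN transcripts differed after siRNA against SNHG5; the series title names miR-92a-3p, CDKN1C and polycystic ovary syndrome. With SNHG5 siRNA, 35 of 39 tested genes of G1/S and DNA replication rose and 23 of 26 tested p53 target genes fell. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 3.55-fold lower, at 515 ± 16.2 CPM with control siRNA and 145 ± 1.96 CPM with SNHG5 siRNA (mean ± SD, n = 3 each). TPM4, which encodes a tropomyosin of the actin cytoskeleton, was 3.95-fold higher, at 350 ± 8.68 and 1380 ± 33.6 CPM. CDKN1C, which encodes the related inhibitor p57, was 3.41-fold lower at a low level, 0.857 ± 0.216 and 0.253 ± 0.180 CPM.

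Of 12508 genes tested, 5026 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2538 higher and 2488 lower with SNHG5 siRNA. The median absolute log2 fold change of the passing genes was 0.33, and 247 of them, 59 higher and 188 lower, had one of at least 1. In 6228 genes (49.8%) the CPM of the groups did not overlap, where chance gives 10% for 3 against 3. Without SNHG5 siRNA replicate 2, 5608 genes passed. With upper quartile scaling 39.9% of the passing genes were higher, against 50.5% with TMM, and across genes the log2 fold change had a Spearman correlation of -0.230 with GC content (genes are not independent replicates).

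**Figure D1:**
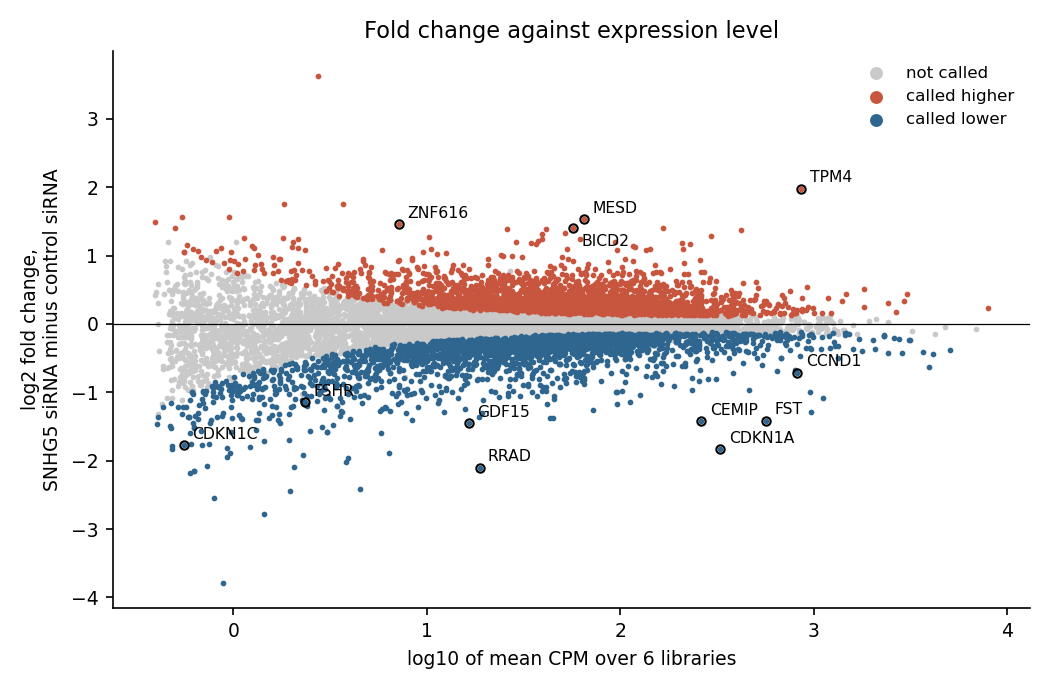
Log2 fold change (SNHG5 siRNA minus control siRNA) of each tested gene against the log10 of its mean CPM over the 6 libraries, with passing genes in red (higher) and blue (lower) and others in grey. TPM4 lies at 1.98, CDKN1A at -1.83 and RRAD at -2.10.

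SNHG5 itself was not analysed here, so the level of the targeted RNA cannot be given. Its gene lies on chromosome 6 from 85660950 to 85678748 on the minus strand (GRCh38, GENCODE v29). Of 15 tested genes within 2 Mb, 9 passed, 7 higher and 2 lower. NT5E, which encodes the ecto-enzyme CD73, rose from 341 ± 12 to 517 ± 17.3 CPM, while SYNCRIP, the nearest gene, had a log2 fold change of -0.04 (adjusted p = 0.534 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and SNX14 had 0.09. From the list of snoRNA host genes, 2 were tested and 0 passed, also when adjusted over the list alone; TAF1D had -0.13 (adjusted p = 0.0895) and C6orf48 -0.12 (adjusted p = 0.153), and C6orf48 had -0.19 with an adjusted p of 0.00388 without SNHG5 siRNA replicate 2.

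CDKN1C (chromosome 11, 2883213 to 2885773, minus strand, protein coding) had 14, 16 and 20 counts with control siRNA and 1, 7 and 7 with SNHG5 siRNA. Its log2 fold change was -1.77 ± 0.49 (SE), with an adjusted p of 0.00690 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The ratio of the groups' counts, scaled to library size, was 0.289 (exact 95% interval 0.151 to 0.523, counting error only). An exact 2-sided permutation test of CPM gave p = 0.1, the smallest that 3 against 3 samples can give. The FPKM were 0.420, 0.489 and 0.623 with control siRNA and 0, 0.382 and 0.320 with SNHG5 siRNA, and with them the log2 fold change no longer passed, at -0.30 (adjusted p = 0.0645) with 1 added and -1.15 (adjusted p = 0.106) with 0.1 added. Without control siRNA replicate 3 it was -1.56 (adjusted p = 0.0516). The annotated 3' UTR of CDKN1C holds the miR-92a-3p site GTGCAAT.

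Of the 6 tested CDK inhibitors, 0 rose, 3 fell and 3 did not pass, the same counts as when adjusted over the list alone. Those that fell were CDKN1A (chromosome 6, 36676460 to 36687339, plus strand), CDKN1C and CDKN1B, which encodes p27 and had a log2 fold change of -0.83. The list's median was -0.50, with an adjusted p of 0.0577 by camera, 0.249 by camera with an estimated correlation and 2.31e-04 by fry. By camera it passed without control siRNA replicate 2 (adjusted p = 0.0494), SNHG5 siRNA replicate 1 (0.0415) or SNHG5 siRNA replicate 2 (0.0398). Over all alternatives its median ranged from -0.52 to -0.16, and with 1 library left out from -0.52 to -0.45.

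Among p53 target genes, 0 rose, 23 fell and 3 did not pass; adjusted over the list alone, 1 rose and 23 fell. The member that rose on its own list was XPC, at 0.14, which over all genes tested did not pass (adjusted p = 0.0873; 0.19 and 0.0163 without SNHG5 siRNA replicate 2). The median log2 fold change was -0.61 (camera adjusted p = 1.73e-11; adjusted p = 0.103 with an estimated correlation). Besides CDKN1A, the largest falls were in GDF15, a secreted stress-induced factor, which was 2.73-fold lower (24.2 ± 0.859 and 8.87 ± 0.552 CPM), and in TP53INP1 (-1.29) and GADD45A (-1.17).

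Genes of G1/S and DNA replication gave 35 higher, 1 lower and 3 not passing of 39, and the same higher and lower counts adjusted over the list alone. Their median was 0.38 (camera adjusted p = 1.73e-11; adjusted p = 0.169 with an estimated correlation). The transcription factor gene E2F1 rose by 0.80 on the log2 scale, from 54.2 ± 3.74 to 94.5 ± 7.47 CPM, POLE2, a subunit of DNA polymerase epsilon, by 0.71, and MCM10, a replication initiation factor, by 0.62. The member that fell was CCND1, cyclin D1 (chromosome 11, 69641087 to 69654474, plus strand), from 1023 ± 18.9 to 625 ± 10.5 CPM, a log2 fold change of -0.71. CCND2 was listed at 0 in every library in both the counts and the FPKM.

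Of 40 tested genes of G2/M and mitosis, 15 rose, 9 fell and 16 did not pass (15 and 10 adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.381; 0.00629 by fry, higher). BIRC5, which encodes survivin, rose by 0.87, MYBL2 by 0.41 and HMMR by 0.35, while CDC20, an activator of the anaphase-promoting complex, fell by 0.40. MKI67, the proliferation marker, fell from 793 ± 64.7 to 644 ± 86.3 CPM, a log2 fold change of -0.30 (adjusted p = 0.00375 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That of MKI67 did not pass DESeq2's test (adjusted p = 0.0575) and was -0.19 without SNHG5 siRNA replicate 2; its 3' UTR holds ACACGAA, a leading word of the scan of 3' UTRs.

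**Figure D2:**
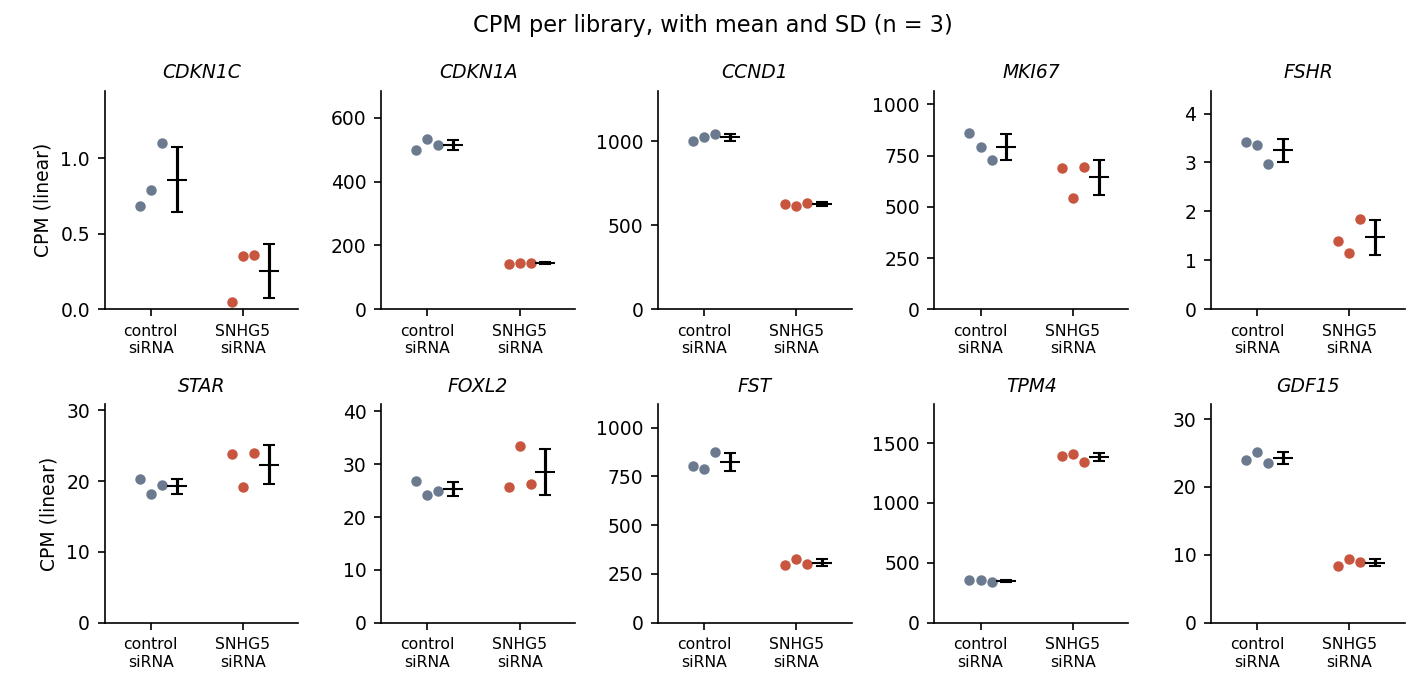
CPM (linear axis from 0) of 10 genes in each library, control siRNA in grey and SNHG5 siRNA in red, with black bars for the mean and SD of 3 libraries. CDKN1A lies at 145 ± 1.96 CPM with SNHG5 siRNA against 515 ± 16.2 CPM with control siRNA, while the libraries of STAR and FOXL2 overlap between groups.

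Among the largest rises of passing genes with a mean CPM of at least 5 were TPM4 (chromosome 19, 16067021 to 16103005, plus strand; log2 fold change 1.98 ± 0.05 SE, adjusted p = 5.57e-16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), MESD, a chaperone of LDL receptor proteins (1.54), and ZNF616 (1.46). Others were BICD2, an adaptor of the dynein motor (1.41), NOLC1, a nucleolar phosphoprotein (1.40), CDK14 (1.38) and GANAB, a glucosidase of the endoplasmic reticulum (1.38). The largest falls were RRAD, a small GTPase (chromosome 16, 66921679 to 66925644, minus strand; -2.10 ± 0.09 SE, from 30.4 ± 0.934 to 7.08 ± 0.817 CPM), CDKN1A, VTN, which encodes vitronectin (-1.59), and GDF15 (-1.45). CEMIP, which takes part in hyaluronan breakdown (-1.42), FST (-1.42), CYP4F11 (-1.41) and ACBD5, a peroxisomal protein (-1.37), followed. CPA4, a carboxypeptidase, had among the smallest p of the falling genes, at 1367 ± 30.1 and 562 ± 28.8 CPM. The 3' UTRs of TPM4, BICD2, NOLC1 and CDK14 hold the word TCGGAGA and that of ACBD5 holds ACACGAA, the leading words of the scan of 3' UTRs.

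Granulosa cell identity and follicle growth genes moved in both directions: of 34 tested, 9 rose, 7 fell and 18 did not pass, also when adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.767). HAS2, the hyaluronan synthase of the expanding cumulus, rose by 1.76, from 0.839 ± 0.184 to 2.83 ± 0.725 CPM, and IGFBP4, an IGF-binding protein, rose from 36.9 ± 0.409 to 87.5 ± 7.85 CPM. FST, which encodes the activin-binding protein follistatin (chromosome 5, 53480409 to 53487134, plus strand), fell from 823 ± 46.6 to 308 ± 18.2 CPM. FSHR, the receptor of follicle-stimulating hormone (chromosome 2, 48962157 to 49154537, minus strand), fell from 3.25 ± 0.242 to 1.47 ± 0.354 CPM, a log2 fold change of -1.15 (adjusted p = 2.32e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). FOXL2, a granulosa transcription factor, had 25.3 ± 1.40 and 28.6 ± 4.33 CPM. Its log2 fold change of 0.17 did not pass (adjusted p = 0.158 by edgeR's quasi-likelihood test). The SNHG5 siRNA mean was raised by replicate 2, at 33.6 CPM, against 25.8 and 26.4 CPM in replicates 1 and 3. With the GC trend removed the log2 fold change was 0.33 (adjusted p = 0.00913) and with the length trend removed 0.22 (0.0337).

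Steroid hormone synthesis genes gave 5 higher, 3 lower and 10 not passing of 18 tested, with 5 higher and 4 lower adjusted over the list alone. Their median was 0.02, their mean -0.0045 and camera's adjusted p 0.767. SRD5A1, a steroid reductase, rose by 0.44, while NR5A2, a nuclear receptor of steroidogenic cells, had -0.93 and FDXR, the mitochondrial reductase that serves steroid-cleaving enzymes and is also on the p53 list, had -0.90. CYP1B1, whose 3' UTR holds TCGGAGA, rose by 1.06 at 0.361 ± 0.125 and 0.752 ± 0.0735 CPM; its call ended when any library other than control siRNA replicate 3 was left out, with 0.84 (adjusted p = 0.169) without control siRNA replicate 2. STAR, which moves cholesterol into mitochondria, had 19.3 ± 1.08 and 22.3 ± 2.70 CPM, a log2 fold change of 0.21 (adjusted p = 0.0734 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 0.31 (adjusted p = 0.00155) without SNHG5 siRNA replicate 2. STAR also passed with no filter, with the replicate block and with the length or GC trend removed, at 0.21 to 0.28. CYP11A1, with 7 counts over the control libraries and 5 over the SNHG5 siRNA libraries, and CYP19A1, with 14 and 22, were too low to be tested.

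Cholesterol synthesis and uptake genes gave 17 higher, 1 lower and 6 not passing of 24, and 18 higher and 1 lower adjusted over the list alone. The median was 0.27 (camera adjusted p = 6.02e-05; adjusted p = 0.179 with an estimated correlation). INSIG1, a regulator of sterol sensing, rose by 0.57 and PMVK, a kinase of the mevalonate pathway, by 0.48, while TM7SF2, a sterol reductase whose 3' UTR holds TCGGAGA, fell by 0.78.

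Integrated stress response genes gave 1 higher, 19 lower and 7 not passing of 27 (2 and 21 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.71e-05; adjusted p = 0.161 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, fell from 46.7 ± 1.10 to 23.3 ± 1.41 CPM, and STC2 (-0.67), SESN2 (-0.53) and the amino acid transporter gene SLC7A5 (-0.49) also fell. TRIB3 rose by 0.16; this call ended without control siRNA replicate 2 (0.14) or 3 (0.15) and without SNHG5 siRNA replicate 1 (0.16) or 3 (0.13).

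NF-kB and inflammatory cytokine genes gave 3 higher, 14 lower and 3 not passing of 20, with the same higher and lower counts adjusted over the list alone and a median of -0.48 (camera adjusted p = 5.33e-04; adjusted p = 0.161 with an estimated correlation). BIRC3, an inhibitor of apoptosis, was 2.48-fold lower and NFKB2, which encodes the precursor of p52, 2.14-fold lower, from 61.7 ± 0.0835 to 28.9 ± 0.207 CPM. Those that rose were SOD2 (0.30), PTGS2 (1.12; 0.92 and not passing without control siRNA replicate 2) and CXCL8 (0.53). The call of CXCL8 ended without control siRNA replicate 1 (0.50) or 3 (0.52) or SNHG5 siRNA replicate 3 (0.43), and that of CXCL2, with -1.21, ended without control siRNA replicate 1 (-1.03) or SNHG5 siRNA replicate 3 (-1.05).

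Interferon response genes gave 2 higher, 19 lower and 13 not passing of 34 (2 and 20 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 3.62e-04; adjusted p = 0.179 with an estimated correlation). BST2, which encodes the antiviral protein tetherin, fell from 0.941 ± 0.197 to 0.275 ± 0.0598 CPM, and OASL (-1.33), MX2 (-1.05) and IFI27 (-0.93) also fell from levels under 5 CPM. IFI44 (0.40) and SAMD9 (0.35) rose.

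WNT pathway and target genes gave 1 higher, 9 lower and 9 not passing of 19, with the same higher and lower counts adjusted over the list alone and a median of -0.22 (camera adjusted p = 9.48e-04; adjusted p = 0.169 with an estimated correlation). LGR5, a receptor of R-spondins, fell from 3.36 ± 0.432 to 0.786 ± 0.195 CPM. DKK1, a secreted WNT antagonist, fell by 0.80 and the ligand gene WNT5A by 0.76. TCF7 had -1.04, with CPM that overlapped between groups, and its call ended without control siRNA replicate 2 (-0.73) or 3 (-0.999) or SNHG5 siRNA replicate 1 (-0.92) or 2 (-0.73), and was -1.56 without SNHG5 siRNA replicate 3. MYC rose by 0.18, and by 0.17 without control siRNA replicate 2, where its call ended.

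Glycolysis genes gave 1 higher (PFKL, 0.41), 14 lower and 8 not passing of 23, and 1 and 16 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 3.98e-04; adjusted p = 0.249 with an estimated correlation). SLC2A3, a glucose transporter gene, fell by 0.48, PDK1, a kinase of pyruvate dehydrogenase whose 3' UTR holds ACACGAA, by 0.46, and GAPDH by 0.44. NRF2 target genes gave 1 higher (ME1, 0.50), 12 lower and 10 not passing of 23, and 1 and 14 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 6.74e-04; adjusted p = 0.461 with an estimated correlation). OSGIN1 fell by 0.56 and GSR, glutathione reductase, by 0.51. Hypoxia response genes gave 1 higher (LOX, 0.55), 12 lower and 8 not passing of 21, the same counts adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0124; adjusted p = 0.655 with an estimated correlation; 0.0506 by fry). EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 1.15, NDRG1 by 0.81 and the carbonic anhydrase gene CA9 by 0.74.

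Ribosomal protein genes gave 0 higher, 42 lower and 40 not passing of 82 (0 and 46 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 3.68e-06; adjusted p = 0.655 with an estimated correlation; 0.116 by fry). RPS19 (-0.30), RPL35A (-0.29), RPL36 (-0.28) and RPL29 (-0.28) fell, and the list's median was -0.08 with the length trend removed. SNHG5 siRNA replicate 2, the library that stood apart, had a Spearman correlation of -0.475 across genes between its deviation from the group mean and gene length, against -0.257 to 0.373 in the other libraries. Among the SNHG5 siRNA libraries, replicate 2 had the highest CPM of RPS19, RPL35A, RPL36 and RPL29, so it lessened their falls. RPS19 had 442, 540 and 443 CPM in replicates 1, 2 and 3. With 1 library left out the list's median ranged from -0.20 to -0.10.

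**Figure D3:**
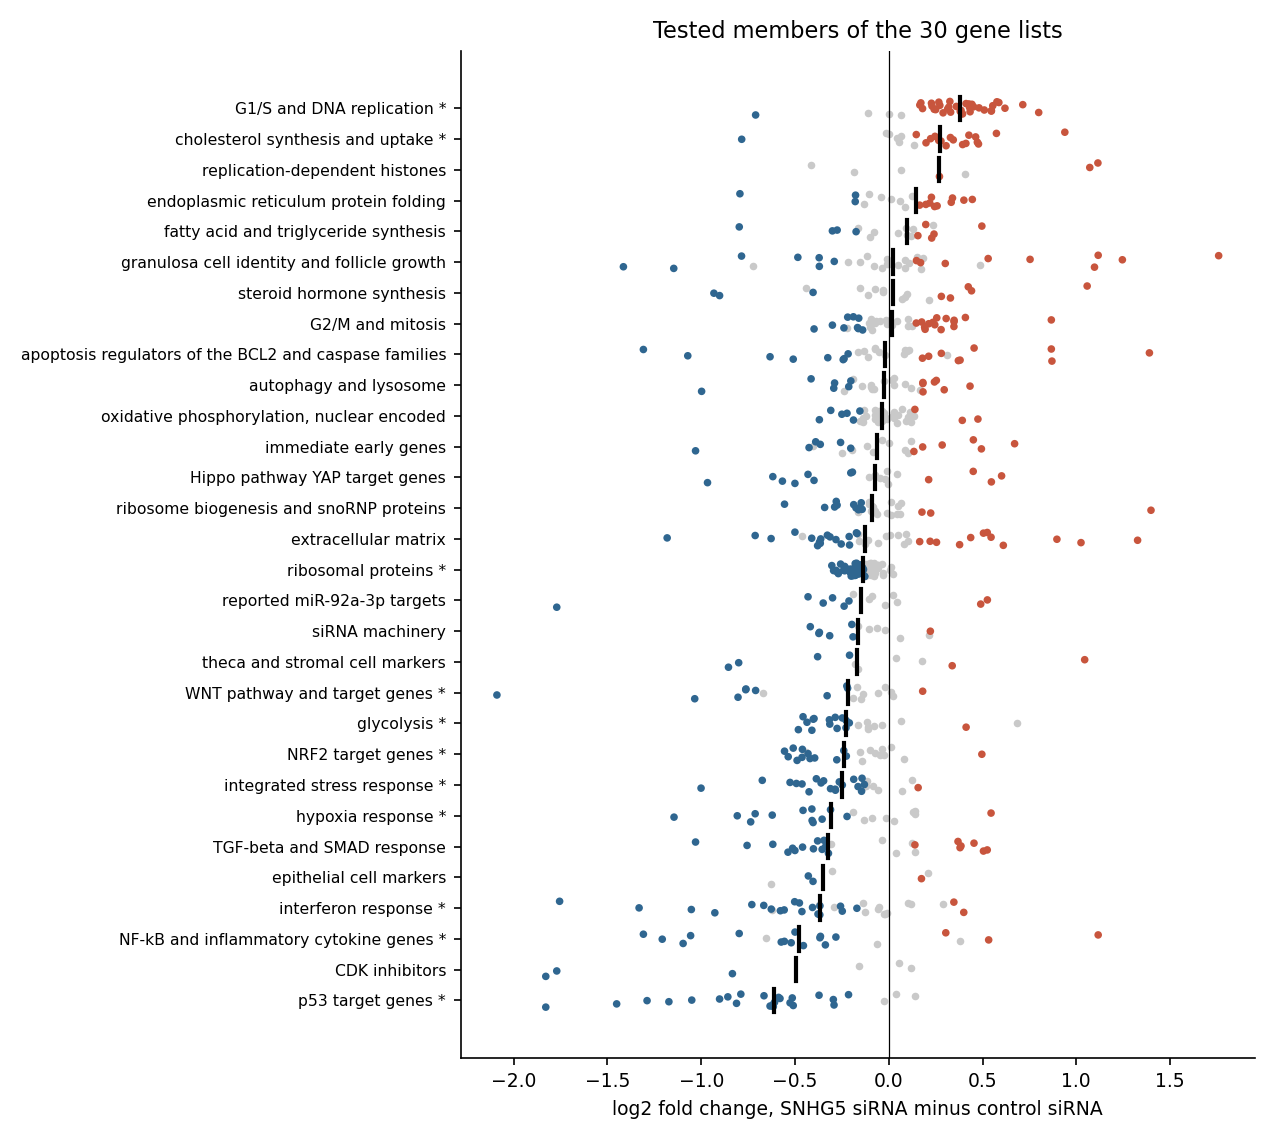
Log2 fold change (SNHG5 siRNA minus control siRNA) of every tested member of the 30 lists with at least 5 tested members, 1 point per gene, with passing genes in red or blue, medians as black bars and an asterisk at the 11 lists that passed camera at the preset correlation; with an estimated correlation 0 passed (smallest adjusted p = 0.103; 7 at an unadjusted p under 0.05). The median lies at -0.61 for p53 target genes and at 0.38 for G1/S and DNA replication.

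Apoptosis regulators of the BCL2 and caspase families gave 9 higher, 8 lower and 12 not passing of 29, also when adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.761). BCL2, which encodes an inhibitor of apoptosis, rose by 0.87, while BIRC3 fell by 1.31. BMF, a pro-apoptotic member, had -1.07, a call that ended without control siRNA replicate 1 (-0.86) or SNHG5 siRNA replicate 3 (-0.85). Genes of the siRNA machinery gave 1 higher, 6 lower and 6 not passing of 13 (2 and 6 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.151). With 1 library left out this median ranged from -0.17 to -0.085. TNRC6B (-0.42), DICER1 (-0.37), TARBP2 (-0.37) and AGO3 (-0.31) fell.

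Theca and stromal cell markers gave 2 higher, 4 lower and 4 not passing of 10 (camera adjusted p = 0.413; 0.0109 by fry, lower), with TAGLN at 1.04, PDGFRB at -0.85 and PTCH1 at -0.80. Epithelial cell markers gave 1 higher (KRT8, 0.17), 2 lower (KRT18, -0.43, and KRT7, -0.40) and 3 not passing of 6 (camera adjusted p = 0.454). Endothelial cell markers gave 0 higher, 1 lower and 3 not passing of 4, with KDR at -1.07 and VWF, which did not pass, at 0.13. Leukocyte markers gave 1 higher, 0 lower and 3 not passing of 4, with LCP1 at 0.45 and CD68, which did not pass, at 0.22 (adjusted p = 0.0508; 0.0426 without control siRNA replicate 1 and 0.0175 without SNHG5 siRNA replicate 2, at 0.27 and 0.23). Sertoli cell markers gave 1 higher, 1 lower and 1 not passing of 3, with SOX9 at 1.00 and CLDN11 at -0.45. Adjusted over the list alone, the counts were the same except for leukocyte markers, with 2 higher. In the passing genes named by list, the CPM of the groups did not overlap, except in TCF7. Passing the test favours such genes, and 49.8% of all tested genes had no overlap. Genes named by size of change were chosen for having none.

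The series title names miR-92a-3p, so genes whose 3' UTR holds its site, GTGCAAT, were compared with the other tested genes. The 1422 genes with the site had a mean log2 fold change 0.030 above that of the 10792 without it (95% interval 0.010 to 0.049 across genes). Of these genes 330 rose and 277 fell, and camera, run on this set alone, gave an unadjusted p of 0.313. With the GC trend removed, the difference was -0.0094 (95% interval -0.029 to 0.0099), and for the 414 genes with the longer site GTGCAATA it was -0.011. Without SNHG5 siRNA replicate 2 it was 0.054. Of 14 tested genes on the list of reported miR-92a-3p targets, 2 rose (DUSP10, 0.53, and KLF2, 0.49), 6 fell and 6 did not pass. The counts were the same when adjusted over the list alone, and the median was -0.15 (camera adjusted p = 0.248). CDKN1C and HIPK3 (-0.43) were among those that fell. The 3' UTRs of DUSP10 and KLF2, which rose, hold GTGCAAT, as do those of CDKN1C and HIPK3.

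In the scan of every word of 7 bases in the 3' UTRs of 12214 tested genes, ACACGAA had the lowest z, -11.7, and TCGGAGA the highest, 8.35. The 254 genes with ACACGAA had a median log2 fold change of -0.23, and 130 of them (51.2%) fell while 25 rose; of genes without the word, 19.4% fell. The 235 genes with TCGGAGA had a median of 0.15, and 100 of them (42.6%) rose while 28 fell; of genes without it, 19.9% rose. The next words were CCCACCC at -10.7 and TTTTAAA at 7.62, which had -3.79 and 1.34 with trends on length and GC content removed. With those trends removed the next words were CACGAAA at -8.47, which overlaps ACACGAA, and AGGAGAA at 7.28. GTGCAAT had a z of 0.797 with the length trend alone removed. Without control siRNA replicate 3, ACACGAA had a z of -11.7 and TCGGAGA 7.6, and other words lay beyond each.

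**Figure D4:**
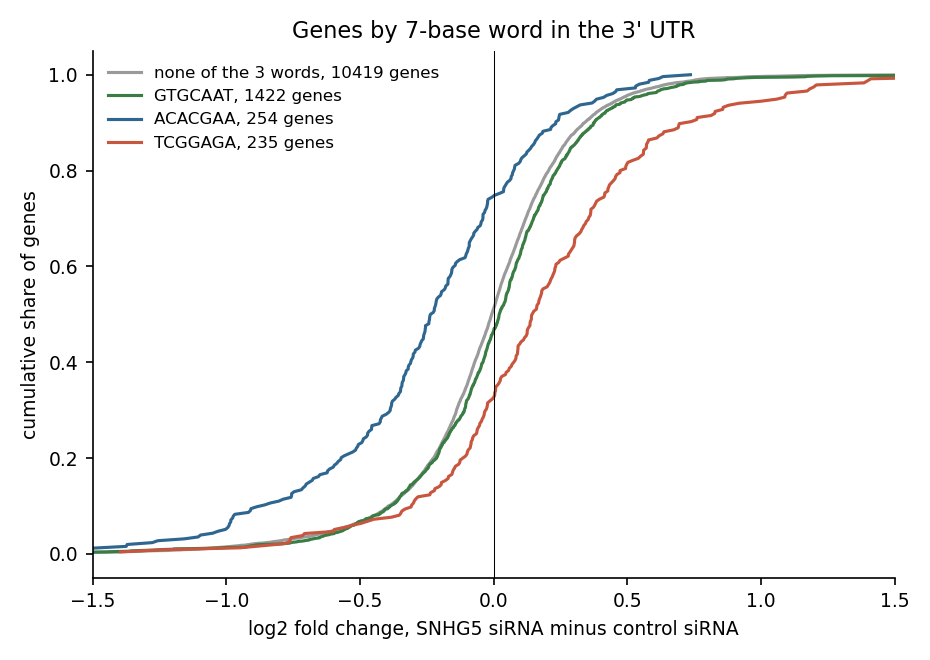
Cumulative share of tested genes against log2 fold change (SNHG5 siRNA minus control siRNA), grouped by 7-base word in the 3' UTR: ACACGAA (254 genes), TCGGAGA (235), GTGCAAT (1422) and none of these (10419). The ACACGAA curve lies to the left, with a median of -0.23, and the TCGGAGA curve to the right, with a median of 0.15.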

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

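The comparison below was chosen after the values had been seen. It concerns genes outside the count-based comparisons: 116 genes had 0 counts in every library and an FPKM above 0, and 35 of these had a mean FPKM of at least 1. In 7 of them, the FPKM of every SNHG5 siRNA library lay above that of every control siRNA library, a signal in data that the comparisons did not use. They were LUZP6 (98.3 with control siRNA and 126 with SNHG5 siRNA, mean FPKM), PIGY (52.4 and 63.3), BCL2L2-PABPN1 (37.4 and 46.4), C7orf55-LUC7L2 (9.15 and 17.1), AARSD1 (10.3 and 11.2), LOC101928589 (5.21 and 6.82) and C15orf38-AP3S2 (4.14 and 5.75). The opposite order held in 3, RPS10-NUDT3 (48 and 42.5), IQCJ-SCHIP1 (16.6 and 14.3) and PPAN-P2RY11 (5.30 and 3.77). Chance gives each order in 1 of 20 genes for 3 against 3. Of the genes tested on counts, 25.0% had every SNHG5 siRNA library above every control library and 24.8% below, so these 35 genes were not parted more often. No explanation was tested.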

How the results depend on the processing

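Tests with GC trends removed, with genes or members holding the leading words left out, and the scan without each library were chosen after the data were seen; the others were planned. No gene that passed both in the reported test and in an alternative changed sign in any alternative fitted to all genes. Of the 143 genes chosen by the rule or singled out, 113 kept their direction and side of the threshold under all 21 settings that gave them a value, 24 lost their call under at least 1 setting, 6 gained one and 0 reversed; log2 of FPKM plus 1 ended 13 calls, DESeq2's test 9 and leaving out control siRNA replicate 2 ended 10. The number of passing genes ranged from 3991 to 5608 (2045 to 2874 higher, 1946 to 2734 lower) when 1 library was left out. It was 5714 with the replicate block, 5609 with the length trend removed and 6011 with both. Libraries of the same replicate number were at most weakly alike in their deviations from the group means (correlations 0.0463, 0.130 and 0.0264 for replicates 1, 2 and 3). Those of replicate 2 were each other's closest match between the groups. The number of passing genes was 5094 with the GC trend removed, 5625 with that and the block, 4478 with DESeq2 and 4748 without genes that hold either leading word. By their own construction, an adjusted p under 0.01 gave 1592 lower and a log2 fold change of at least 1 gave 247 (59 higher, 188 lower). Limma on log2 of FPKM plus 1 gave 1723 lower, and 1526 with the FPKM minimum of 1; the cause was not tested.

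CDKN1C ranged from -2.12 to -1.24 with 1 library left out and was -0.30 and -1.15 on log2 of FPKM plus 1 and plus 0.1, where it missed the threshold. Its FPKM were at most 0.623, so adding 1 shrinks the log2 fold change by construction. Why CDKN1C missed the threshold on FPKM was not tested. It had too few counts or FPKM to be tested under the minimum of 1 CPM or 1 FPKM, and SNHG5 had no value under any setting. With an estimated correlation 0 lists passed, against 11 to 13 with 1 library left out. Medians that changed sign belonged to lists that did not pass: steroid hormone synthesis (-0.033 with at least 1 CPM, -0.030 without members with the words), autophagy and lysosome (0.020 with the length trend removed, 0.0048 with the GC trend removed, 0.0053 with that and the block, -0.082 to 0.032 with 1 library left out), oxidative phosphorylation (0.017, length), G2/M and mitosis (-0.028, GC; -0.027, GC and block), apoptosis regulators (-0.043 to 0.029, 1 library left out) and immediate early genes (-0.074 to 0.0019, likewise); the cause was not tested. The miR-92a-3p difference was -0.0094 with the GC trend removed, -0.0098 with that and the block, -0.011 for the longer site and 0.018 to 0.054 with 1 library left out. The z of ACACGAA ranged from -11.7 to -11.2 and that of TCGGAGA from 7.6 to 8.62 with 1 library left out. Depth limits genes near the floor of 0.136 to 0.165 CPM, such as CDKN1C, more than the rest.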

Other observations

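Of the tests below, the comparison of the words with SNHG5 and with a control duplex, the splits of the libraries for genes and words, the count ratio of CDKN1C, the test of miR-92a-3p site genes as its cause and the count of fallen p53 target genes with neither word were chosen only after the results were seen, as were the gene families and, as added settings, the removal of GC trends and of genes with the words. Extracellular matrix genes gave 12 higher, 17 lower and 12 not passing of 41 (12 and 20 adjusted over the list alone; median -0.13; camera adjusted p = 0.454). LAMA4, a laminin chain, rose from 29.6 ± 0.859 to 74.2 ± 5.65 CPM, COL6A3 by 1.02 and TNC, tenascin C, by 0.90; BGN had -1.18, a call that ended without control siRNA replicate 1 (-1.10) or 2 (-1.10) or SNHG5 siRNA replicate 1 (-1.01) or 3 (-1.03). TGF-beta and SMAD response genes gave 7 higher, 13 lower and 5 not passing of 25 (9 and 14 adjusted over the list alone; median -0.32; camera adjusted p = 0.151; 5.14e-04 by fry), with JUNB at -1.03, LTBP3 at -0.76, TGFB2 at -0.62 and SKIL at -0.54. Hippo pathway YAP target genes gave 4 higher, 8 lower and 7 not passing of 19, also when adjusted over the list alone (median -0.07; camera adjusted p = 0.192; 0.0110 by fry), with ANKRD1 at -0.97, AMOTL2 at -0.57 and NT5E at 0.60. Immediate early genes gave 6 higher, 6 lower and 10 not passing of 22, also when adjusted over the list alone (median -0.06; camera adjusted p = 0.9), with JUNB, also on this list, at -1.03, DUSP5 at 0.67, IER2, whose 3' UTR holds TCGGAGA, at 0.49 and KLF6 at 0.45.

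Endoplasmic reticulum protein folding genes gave 10 higher, 3 lower and 7 not passing of 20, also when adjusted over the list alone (median 0.14; camera adjusted p = 0.0807; 3.08e-04 by fry). The chaperone gene CALR rose from 1249 ± 39.4 to 1701 ± 35.5 CPM, with SDF2L1 at 0.40 and CRELD2 at 0.34, while the stress sensor gene ERN1 fell by 0.79. Fatty acid and triglyceride synthesis genes gave 5 higher, 4 lower and 9 not passing of 18, also when adjusted over the list alone (median 0.10; camera adjusted p = 0.761), with ME1, also an NRF2 target gene, at 0.50, SREBF1 at -0.30 and GPAM at -0.28; DGAT2 had -0.80, a call that ended without control siRNA replicate 1 (-0.74) or 2 (-0.73) or SNHG5 siRNA replicate 2 (-0.62). Nuclear-encoded oxidative phosphorylation genes gave 3 higher, 6 lower and 34 not passing of 43 (2 and 5 adjusted over the list alone; median -0.03; camera adjusted p = 0.675), with NDUFB5 at 0.39 and NDUFB10 at -0.37. Autophagy and lysosome genes gave 7 higher, 6 lower and 14 not passing of 27, also when adjusted over the list alone (median -0.03; camera adjusted p = 0.761); SQSTM1, the autophagy receptor p62, fell from 1272 ± 42.7 to 637 ± 21.7 CPM and BECN1 rose by 0.43. Ribosome biogenesis and snoRNP protein genes gave 3 higher, 11 lower and 16 not passing of 30, also when adjusted over the list alone (median -0.09; camera adjusted p = 0.101, and 0.0398 without SNHG5 siRNA replicate 2), with NOLC1 at 1.40, NOP2 at -0.56 and RRP9 at -0.34. Replication-dependent histone genes gave 3 higher, 0 lower and 4 not passing of 7, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.417). With 1 library left out their median ranged from 0.17 to 0.57. HIST1H2BD rose by 1.12. The calls of HIST1H1C (0.27) and HIST1H2BK (1.07) each ended without control siRNA replicate 2 (0.27 and 1.17) or SNHG5 siRNA replicate 2 (0.17 and 0.84), that of HIST1H1C also without control siRNA replicate 1 (0.22), and that of HIST1H2BK without control siRNA replicate 3 (0.74) or SNHG5 siRNA replicate 3 (1.06). The list of mRNAs encoded by mitochondrial DNA was not analysed here. Among 145 gene families formed from symbols, 3 passed camera: MCM (8 higher and 0 lower of 10; median 0.27; adjusted p = 0.00483), RAD (8 and 1 of 18; 0.19; 0.0215) and RPL (3 and 22 of 48; -0.13; 0.0322); with an estimated correlation the adjusted p of each was 0.993.

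None of the other 9 splits of the 6 libraries gave a gene past the threshold by edgeR's quasi-likelihood test (57 to 501 genes had an unadjusted p under 0.05), against 5026 for the real split, which alone of 10 (1 of 10) gave as many. For the gene lists, 2 of the 10 splits gave at least the real 11, and the highest other split gave 12. With 10 splits the share cannot be under 0.05. Each other split also mixes libraries of both groups, so the difference between the groups widens its spread. That none of them gave a passing gene is therefore no measure of chance, and 5026 cannot be judged against it.

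The words ACACGAA and TCGGAGA led the scan in opposite directions. With trends on 3' UTR length and GC content removed, they still had the most extreme z of their directions (-11.6 and 9.67), which argues against 3' UTR composition as the whole cause. Genes with ACACGAA only outside the 3' UTR lay 0.177 (SE 0.030) above those with it in the 3' UTR, at a shift of their own of -0.0857 (SE 0.0138), which argues against action elsewhere in the transcript as the whole cause, and 17 of 23 annotated SNHG5 transcripts hold ACACGAA (chromosome 6, 85678024 to 85678030) where 14.9% of all 7-base words occur in SNHG5, so seed pairing of an SNHG5 siRNA strand with unintended 3' UTRs may have lowered these genes. TCGGAGA, at a z of 8.35, is the site of bases 2 to 8 of a control duplex's sense strand. That duplex is widely sold, and its sequence was taken from general knowledge. Seed pairing of the control siRNA may thus have lowered the genes with TCGGAGA in the control libraries. TGTCACG, the antisense strand's site, had a z of only 2.56 (3.67 with trends removed). The labels give neither siRNA sequence. Of the passing genes, 278 (5.62% of those with a 3' UTR) hold either word, as do 480 of all 12214 tested genes with a 3' UTR. The count covers these 2 words alone, with no other site and no indirect effect. The absolute z of ACACGAA was 11.7 in the real split (1 of 10 as large) and at most 9.17 in the others. These are too few splits for a share under 0.05. Each other split also mixes the groups and keeps part of their difference, so it is no measure of chance alone. In 100 shuffles of the genes the absolute z was at most 5.15. GC-rich words, however, reached 13.3 to 14.6 in the 3 splits that set control siRNA replicate 3 apart from its replicates. That library's deviation from its group mean had a Spearman correlation of -0.468 with GC content across genes. The splits were scanned without removal of that trend. The shuffles keep no trend that genes share, so they left chance association across genes open.

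The p53 target genes fell together. Of the 23 members that fell, 22 hold neither word in the 3' UTR. This argues against direct action through the words in the members' own 3' UTRs as the whole cause. Only 480 of 12214 tested genes with a 3' UTR hold either word, so few members could be expected to. The count cannot tell whether either siRNA acted on these genes through other genes. With the GC trend removed the list's median was -0.59, still past camera's threshold at the preset correlation (without the removal, adjusted p = 0.103 with an estimated correlation), which argues against that trend as the whole cause. A response of these genes to the control siRNA, and not to the SNHG5 siRNA, remains open, since the series holds 0 untransfected libraries; the effect of less SNHG5 was not tested separately from that of the siRNA.

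CDKN1C was lower with SNHG5 siRNA. The upper bound of the exact interval of its count ratio was 0.523, which argues against counting noise, and its log2 fold change was -1.62 with the GC trend removed, which argues against that trend. Freed miR-92a-3p may have acted on it, but genes with the miRNA's site lay 0.030 above the others (95% interval 0.010 to 0.049), and -0.0094 (-0.029 to 0.0099) with the GC trend removed, so these genes as a set did not decide. An effect of less SNHG5 on CDKN1C was not tested separately from unintended effects of either siRNA.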
